A study of Mus musculus with 12 samples.

How the data were processed

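Gene expression was measured in cardiac muscle of male NMRI mice with Affymetrix MG_U74Av2 oligonucleotide arrays, 1 array for each of 4 conditions at 1, 3 and 5 weeks, 12 arrays in all. An age of 10 to 15 weeks is given for the mice of every array alike, and not by week. Per the labels' protocols, diabetes was induced with a single injection of streptozotocin (180 mg/kg), which destroys insulin-producing beta cells, and control mice received buffer. Trained mice ran on a treadmill for 1 h per day on 5 days per week at 21 m/min and 2.5 degrees of incline, and hearts were taken 24 h after the last bout. Each condition and week had 5 mice, whose RNA was pooled before labelling, so each array holds 1 pool and no array holds a single animal. The p-values therefore measure how much a condition's effect varied between the pools of weeks 1, 3 and 5, and not the spread between animals.

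The deposited values are probe set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. In the deposited table the trimmed mean of every array lies between 50.03 and 50.04, so each array had been scaled to a common mean of 50. An experiment file per array gave the scan day, chip lot, fluidics module and comments, and was read for batches alone. Run day and week fell together, except that the diabetic trained array of week 3 was scanned on a day of its own with a chip lot of its own; its comment records that the same RNA was labelled again after a first array with high background. The 12 arrays took 4 run days and 3 chip lots. Arrays of week 5 shared a lot that no other week used, so week 5 cannot be told apart from that lot and day. Each condition was run on its own fluidics module, so condition and module cannot be told apart.

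The table holds 12488 probe sets, of which 66 are controls and were left out of the tests. Of the other 12422, 10833 have 1 gene symbol in the array annotation, 396 have several and 1193 have none. For 10817 the symbol was taken through its gene identifier from the RefSeq table of assembly GRCm38.p6; no coordinates were used. A probe set with several symbols was never given a name. Identifiers ending in _f_at mark probe sets that can share probes with related sequences, so a level from them can hold signal of a near relative.

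Signals under 4.1, the 20th percentile of all values, were set to 4.1, and log2 was taken. Probe sets whose mean log2 signal was at or above the 40th percentile (a geometric mean signal of 11.6) were tested, 7453 probe sets of 5657 named genes. A linear model with condition and week as factors was fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend, in R 4.3.3) to all 12 arrays, with 6 residual degrees of freedom. The comparisons were diabetes over both training states and training over both disease states (6 arrays against 6), the 4 pairwise comparisons (3 against 3), the diabetes by training interaction, week 5 against week 1 (4 against 4), and, with 5 residual degrees of freedom, a linear change of the diabetes effect per week. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Differences are log2 differences between group means after removal of week, with the standard error of the fit; means and SDs of signals are on the linear scale. Differences at a single week set 1 array against 1 and were not tested.

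Lists of genes known from the heart, from diabetes and exercise, and of cell types a heart sample can hold were fixed before the data were examined. Of 37 lists, 36 had at least 3 measured genes and were tested with limma's camera (preset inter-gene correlation of 0.01, 2-sided, adjusted over the lists), and again with an estimated correlation; no list passed in any comparison with the estimated one. Each gene entered with its probe set of highest mean signal. Genes were named by a rule fixed in advance: the probe sets past the threshold with the same sign in every week-matched difference, ranked by size (12 in each direction for diabetes over both training states, 8 or 5 for the others), with genes of smallest unadjusted p given as values where fewer passed, and up to 4 members of each list. A gene outside this rule is said to be so where it is named.

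Week was a block in the model because mice of one week were killed together per the labels and their arrays run on the same day per the experiment files, except for the diabetic trained array of week 3, which shares only the week. Deviations of the arrays from their condition means correlated over probe sets at 0.080 to 0.640 for the 18 pairs of different conditions and the same week (median 0.27), and at -0.452 to 0.246 for the 36 pairs of different weeks (median -0.214). Because the deviations of a condition cancel over its weeks, positive values within a week push those between weeks below zero. The latter are therefore no separate support for the block.

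The alternatives were a fit without week, quantile normalization, centring each array on its median, no filter or a stricter filter on dim probe sets, no floor, an offset in place of the floor, eBayes without a trend, array weights, only the arrays of the groups compared, the scan day as a block, an adjusted p under 0.10, leaving out each array and each week in turn, the mean over a gene's probe sets, an estimated correlation for the lists, and a training by week term beside the slope. The procedure was tested on simulated data of 7453 probe sets, 100 changed by 2-fold and 100 by 4-fold. The spread of each probe set was the moderated one from the fit of the 11 arrays without diabetic trained week 3. It is drawn toward the intensity trend that the tested method assumes, which may raise the recovery. Noise was independent between probe sets and scaled by 1 factor on that array. The shift of that array with signal strength, given below, was not simulated, so recovery in the real data may be lower. For diabetes over both training states it recovered 76% and 96%, for training over both disease states 86% and 98%, for diabetic sedentary against healthy sedentary 56% and 92%, for healthy trained against healthy sedentary 44% and 89%, for diabetic trained against diabetic sedentary 49% and 93%, and for the interaction 18% and 71%. For the change of the diabetes effect with week, it recovered 1% of changes that reached 2-fold over 4 weeks and 40% of those that reached 4-fold. The precision is limited by the number of arrays.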

Results

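Cardiac muscle was compared between healthy and streptozotocin-diabetic mice, sedentary or trained on a treadmill for 1, 3 or 5 weeks. Healthy sedentary, healthy trained, diabetic sedentary and diabetic trained hearts each had 3 arrays, 1 per week. Each array held the pooled RNA of 5 mice. The design asks how diabetes and training, alone and combined, change gene expression in the heart, and whether this depends on time. Median signals lay between 16.6 and 20.4 on 11 arrays and at 25.4 on the diabetic trained array of week 3. That array correlated with the other 11 at a mean r of 0.785 over probe sets, against 0.900 to 0.931 for the others. At week 3 it was at least 2-fold apart from the healthy trained array in 2007 probe sets and from the diabetic sedentary array in 2066. The other 10 week-matched pairs differed in 286 to 603. Because of this array, some results are also given without it.

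Diabetes over both training states raised the slow myosin transcript Myh7 and single transcripts of fuel use, among them Pdk4, Acot1, Ucp3 and Decr1. Myh7, the slow beta-myosin heavy chain, was 3.07-fold higher in diabetic hearts (log2 difference 1.62, SE 0.11, adjusted p = 8.0e-05). Its mean signal was 3177 ± 701 (SD, n = 6) against 1049 ± 285 (n = 6), and a second Myh7 probe set passed too (1.78, SE 0.28). Both Myh7 probe sets are of the _f_at type, so signal of a related myosin is not excluded. Pdk4, a kinase that shuts off pyruvate dehydrogenase, was 3.36-fold higher at 1349.8 ± 322 against 403 ± 102 (1.75, SE 0.15, adjusted p = 0.000305, n = 6 each). Ccn2, a matricellular growth factor, rose 2.97-fold (1.57, SE 0.14), Mt2, a metallothionein, 2.74-fold (1.45, SE 0.20), and Fkbp5, a glucocorticoid-induced co-chaperone, 2.67-fold (1.42, SE 0.16). Fbp2, the muscle fructose bisphosphatase (1.33, SE 0.18), and Acot1, an acyl-CoA thioesterase (1.20, SE 0.16), rose as well. So did Ucp3, a mitochondrial uncoupling protein (0.93, SE 0.18), Txnip, an inhibitor of thioredoxin and glucose uptake (0.87, SE 0.15), and Decr1, an enzyme of unsaturated fatty acid oxidation (0.83, SE 0.15). All of these were higher in 6 of 6 week-matched differences, which the rule for naming required.

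Igtp, an interferon-induced GTPase, rose unevenly with diabetes (1.80, SE 0.33), with week-matched differences from 0.75 to 3.56. Map3k6, a stress-activated kinase, rose too (1.97, SE 0.39), but its mean signal in healthy hearts, 9.47, lay under the highest signal of bacterial and yeast control probe sets, 13.8, so its fold is uncertain. The heat shock genes Hspa1b (-2.21, SE 0.43) and Hsph1 (-1.50, SE 0.23) and the chaperone partner Fkbp4 (-0.81, SE 0.12, an _f_at probe set) fell. Hspa1b was uneven among healthy hearts, at 121 ± 136 against 19.7 ± 7.86 in diabetic hearts (SD, n = 6 each), and its differences ran from -4.83 to -0.22. Aqp1, a water channel of capillary endothelium (-1.29, SE 0.21), Cpxm2, a carboxypeptidase-like protein (-1.28, SE 0.25), and Ccnd1, cyclin D1 (-0.91, SE 0.18), fell. Also lower were Ltbp4, a binder of latent TGF-beta (-0.84, SE 0.16), Cdh13, T-cadherin (-0.83, SE 0.14), Cacna2d1, a calcium channel subunit (-0.83, SE 0.15), and Mrpl45, a mitochondrial ribosomal protein (-0.77, SE 0.14). A second Cpxm2 probe set passed too, and those of Txnip (0.28), Fkbp4 (-0.32), Ccnd1 (-0.89) and Mrpl45 (-0.38) had the same sign and did not pass. Camk2b, a calmodulin-dependent kinase (-1.46, SE 0.20), and Egf, a growth factor (-1.12, SE 0.22), fell to mean signals of 13.3 and 11.6, under the highest control signal.

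In all, 57 probe sets of 52 named genes passed for diabetes over both training states by limma, 28 higher and 29 lower, each with the same sign in 6 of 6 week-matched differences. At an unadjusted p under 0.05 there were 878, where 373 would be expected by chance. Centring the arrays on their medians gave 12 probe sets, 8 higher and 4 lower. Without week as a block 10 passed, without the filter on dim probe sets 6, without a trend in eBayes 9 and with array weights 192. Without the diabetic trained array of week 3 there were 153 (104 higher, 49 lower), which held all 57, and without that of week 1 there were 99. Leaving out an array of week 1 gave 5 (diabetic sedentary), 11 (healthy sedentary) and 16 (healthy trained). For week 3 the counts were 11 (diabetic sedentary), 6 (healthy sedentary) and 10 (healthy trained), and for week 5 they were 43 (diabetic sedentary), 20 (diabetic trained), 7 (healthy sedentary) and 6 (healthy trained).

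Without all of week 1, 3 or 5, the diabetes effect was left with 7, 38 and 0 probe sets. Pdk4, Myh7 and Ccn2 passed in every other fit and missed the threshold without week 5 (adjusted p = 0.0506 for each). Fkbp5 passed without any single array, and lost the call without week 1 (adjusted p = 0.1), without week 5 (adjusted p = 0.0872) and without the filter on dim probe sets (adjusted p = 0.0613). The other 20 genes lost the call in 4 or more of the 15 fits without an array or a week. These were 4 or 5 fits for Fbp2, Acot1, Mt2 and Camk2b, and 8 to 11 for Fkbp4, Aqp1, Decr1, Hsph1 and Txnip. They were 12 to 14 for Cdh13, Cpxm2, Hspa1b, Ltbp4, Map3k6, Ucp3, Ccnd1, Igtp, Mrpl45, Cacna2d1 and Egf. The direction of every named gene held in all of them, which was likely from the naming rule, as it required the same sign in every week-matched difference.

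**Figure D1:**
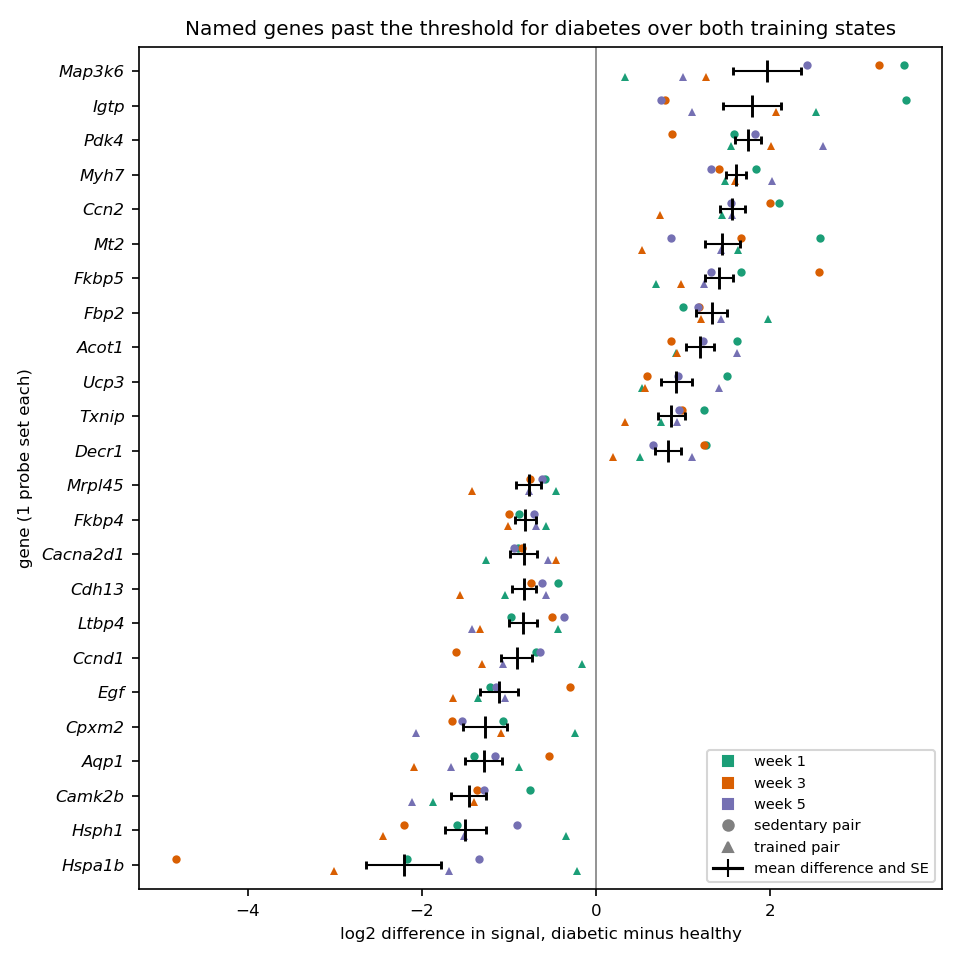
Log2 difference in signal, diabetic minus healthy (x axis), for the 24 genes named for diabetes over both training states (y axis). Circles are the sedentary pairs and triangles the trained pairs of weeks 1, 3 and 5 (1 array against 1). Black bars are the mean difference with its SE. The 6 points of each gene lie on the same side of 0, which the rule for naming required, and those of Myh7 lie between 1.33 and 2.02.

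Lists of lipid use passed for diabetes. In the list of PPARalpha and fasting-response lipid genes, 3 of 12 measured genes rose (Pdk4, Acot1 and Ucp3), 0 fell and 9 did not pass. Adjusted over the list alone 5 were higher and 1 lower, and the median difference was 0.30 (camera adjusted p = 7.9e-05, adjusted p = 0.181 with an estimated correlation). In the list of fatty acid uptake and beta-oxidation, Decr1 rose and 19 of 20 did not pass. Adjusted over the list alone 3 were higher and 1, Cpt2, a carnitine transferase, lower, with a median of 0.15 (adjusted p = 0.00141, adjusted p = 0.581 with an estimated correlation). The list of fatty acid synthesis fell (median -0.27, adjusted p = 0.00141, adjusted p = 0.208 with an estimated correlation). In it Thrsp, a lipogenic regulator, fell (-0.60, SE 0.12) and 8 of 9 did not pass. Adjusted over the list alone 4 were lower, among them the lipogenic enzymes Scd1 (-0.95, SE 0.23) and Fasn (-0.50, SE 0.13). Adipocyte markers, given below, were higher beside these lists (median 0.39), with medians above 0 in 6 of 6 week-matched pairs (0.08 to 0.58).

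The lists of glucose use and of oxidative phosphorylation passed for diabetes with medians under 0, and 0 genes passed in either. In the list of glucose uptake, glycolysis and glycogen none of 24 genes passed by limma. Adjusted over the list alone 5 were lower, such as the glycolytic enzymes Eno3 (-0.53, SE 0.12) and Hk2 (-0.48, SE 0.12), and Pdk1, an inhibitor of pyruvate dehydrogenase, was higher (0.44, SE 0.11). The median of that list was -0.17 (adjusted p = 0.00228, adjusted p = 0.587 with an estimated correlation). The list of oxidative phosphorylation had a median of -0.11 over 57 genes, with 0 past the threshold over all probe sets and 0 adjusted over the list alone (adjusted p = 0.00768, adjusted p = 0.722 with an estimated correlation). Its median was -0.49 in the trained pair of week 3, against -0.10 to 0.03 in the other 5 pairs. Its call was lost without the diabetic trained array of week 3 (median -0.04, adjusted p = 0.648), without the healthy sedentary array of week 3 (adjusted p = 0.0731) and without all of week 3 (adjusted p = 0.576).

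Stress and hormone response lists also moved with diabetes. The glucocorticoid and FoxO response list rose, with a median of 0.41 over 19 genes (adjusted p = 9.8e-08, adjusted p = 0.181 with an estimated correlation). Fkbp5 passed over all probe sets, 18 did not, and 8 were higher adjusted over the list alone, among them Bnip3, a mitophagy receptor (0.65, SE 0.13), and the transcription factors Zbtb16 (0.56, SE 0.12) and Cebpd (0.89, SE 0.21). The heat shock and chaperone list fell, with a median of -0.31 over 21 genes (adjusted p = 1.4e-05, adjusted p = 0.517 with an estimated correlation). Hsph1 and Hspa1b passed, 19 did not, and 4 were lower adjusted over the list alone. Of 26 genes of the antioxidant and metallothionein list, Mt2, Txnip and Cat, catalase (0.80, SE 0.13), rose and 23 did not pass. Adjusted over the list alone 6 were higher, with a median of 0.10 (adjusted p = 0.0065, adjusted p = 0.45 with an estimated correlation), and the call was lost without week 5, where the median was -0.00664 (adjusted p = 0.0723). The interferon and antigen presentation list had a median of 0.38 over 22 genes, with 0 past the threshold and 0 adjusted over the list alone (adjusted p = 0.000861, adjusted p = 0.628 with an estimated correlation). Its call was lost without week 1 (adjusted p = 0.776).

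Matrix and fat cell lists completed the 12 lists that passed for diabetes. The collagens and extracellular matrix list fell (median -0.20, 32 genes, adjusted p = 0.00874, adjusted p = 0.587 with an estimated correlation). Col4a1, a basement membrane collagen, fell (-0.56, SE 0.10), 31 did not pass, and 9 were lower adjusted over the list alone, such as the fibrillar collagens Col1a1 (-1.01, SE 0.24) and Col3a1 (-0.91, SE 0.24). The list of matrix proteases, inhibitors and TGF-beta rose (median 0.17, 14 genes, adjusted p = 0.00945, adjusted p = 0.181 with an estimated correlation). Ccn2 and Timp3, an inhibitor of matrix proteases (0.52, SE 0.10), rose, 12 did not pass, and adjusted over the list alone 4 were higher and 1 lower. Adipocyte markers had a median of 0.39 over 8 genes, with 0 past the threshold (adjusted p = 0.00332, adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone 3 were higher, among them Lipe, hormone-sensitive lipase (0.88, SE 0.20), and Fabp4, a fatty acid binding protein (0.73, SE 0.17), and 1 lower, Car3.

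The calls of these matrix and fat cell lists were less stable than those of the lipid lists. The collagens and extracellular matrix list lost the call without the diabetic trained arrays of week 3 (adjusted p = 0.0691) or 5 (adjusted p = 0.0527), without week 3 (adjusted p = 0.179) or 5 (adjusted p = 0.0635), and with quantile normalization (adjusted p = 0.078). The list of matrix proteases, inhibitors and TGF-beta lost it without the diabetic trained array of week 3 (adjusted p = 0.0691) and without week 1 (adjusted p = 0.13), and adipocyte markers without week 5 (adjusted p = 0.0522). Macrophage and neutrophil markers (median -0.09, 11 genes), endothelial markers (median -0.06, 10 genes) and fibroblast markers (median 0.01, 11 genes) did not pass.

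**Figure D2:**
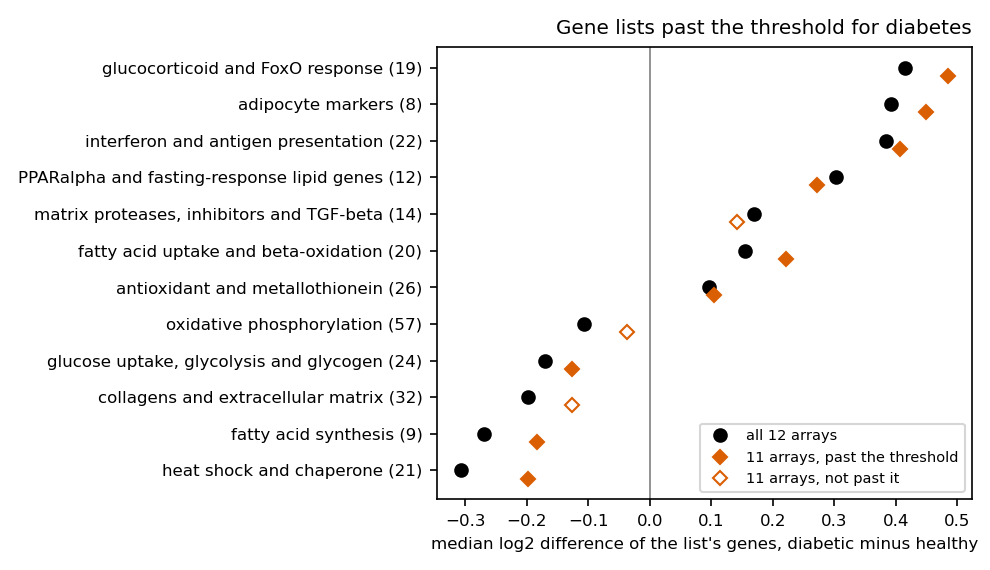
Median log2 difference, diabetic minus healthy (x axis), of the 12 gene lists past the threshold for diabetes over both training states (y axis, number of measured genes in brackets). Black circles are from all 12 arrays. Diamonds are from 11 arrays, without the diabetic trained array of week 3, and open where the call was lost. Oxidative phosphorylation moved from -0.11 to -0.04.

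In sedentary hearts alone, diabetes raised the same leading transcripts. These arrays also entered the comparison over both training states, so the overlap in genes and lists is partly built in. Ccn2 was 3.71-fold higher in diabetic than in healthy sedentary hearts (log2 difference 1.89, SE 0.20, adjusted p = 0.00299), at 615 ± 174 against 165 ± 36.9 (SD, n = 3 each). Fkbp5 rose 3.62-fold (1.86, SE 0.23, adjusted p = 0.0113), Myh7 2.89-fold (1.53, SE 0.16, adjusted p = 0.00299) and Pdk4 2.71-fold (1.44, SE 0.21, adjusted p = 0.0401), each in 3 of 3 weeks. The second Myh7 probe set did not pass here (1.67, SE 0.39). Among genes that did not pass, Mt2 was at 908 ± 288 against 277 ± 80.9, and Acss1, a mitochondrial acetyl-CoA synthetase, at 586 ± 76.6 against 323 ± 5.65. Hsd17b11, a lipid droplet dehydrogenase, was at 160 ± 10.4 against 77.7 ± 13.2 and Slc3a2, an amino acid transporter chain, at 151 ± 22.9 against 80.03 ± 8.41. All 4 had adjusted p = 0.0643. Fkbp4 (-0.86, SE 0.17), Lpin1, a lipid phosphatase (-0.69, SE 0.14), Hsph1 (-1.57, SE 0.33) and Hspa1b (-2.78, SE 0.61) had the smallest p among lower values, with adjusted p from 0.126 to 0.17.

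Of the lists, 6 were higher and 4 lower in diabetic sedentary hearts, 9 of them among those that passed for diabetes over both training states. The 18S ribosomal RNA control was also lower in diabetic than in healthy sedentary hearts at weeks 1 (80.9 against 322), 3 (132 against 1141) and 5 (1395 against 3809). The glucocorticoid and FoxO response list rose (median 0.39, adjusted p = 5.1e-06, adjusted p = 0.335 with an estimated correlation), with 1 of 19 genes past the threshold and 5 higher adjusted over the list alone. The interferon and antigen presentation list rose (median 0.53, adjusted p = 6.5e-05, adjusted p = 0.487 with an estimated correlation), with 0 of 22 past the threshold and 0 adjusted over the list alone. Its call was lost without week 1 (median 0.07, adjusted p = 0.451), without healthy sedentary week 1 (median 0.25, adjusted p = 0.109) and without diabetic sedentary week 1 (median 0.16, adjusted p = 0.106). The list of matrix proteases, inhibitors and TGF-beta passed (median 0.18, adjusted p = 0.0325, adjusted p = 0.335 with an estimated correlation). It lost the call with the same sign in 4 of the 15 fits without an array or a week. Without healthy sedentary week 1 it was lost at a median of -0.000169 (adjusted p = 0.129). Fatty acid synthesis (median -0.17, adjusted p = 0.0483, adjusted p = 0.413 with an estimated correlation) lost it in 10. Glucose use (median -0.15, adjusted p = 0.0478, adjusted p = 0.673 with an estimated correlation) lost it in 8. Without the diabetic trained array of week 3, matrix proteases and fatty acid synthesis lost it (adjusted p = 0.0639 and 0.0757) with unchanged medians. The list outside the 9 was that of lung markers (median -0.89, 3 genes, adjusted p = 0.00619, adjusted p = 0.335 with an estimated correlation). None of its genes passed, 1 was lower adjusted over the list alone, and the call was lost without week 3 (adjusted p = 0.129). Without healthy sedentary week 3 alone its median was -0.33 (adjusted p = 0.0459).

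Ccn2, Fkbp5, Myh7 and Pdk4 were all that passed for diabetic sedentary against healthy sedentary by limma, with 546 probe sets at an unadjusted p under 0.05. Without the diabetic trained array of week 3, which enters only the estimates of spread and week, 60 passed (44 higher, 16 lower), these 4 among them, and 1015 had an unadjusted p under 0.05. When only the 6 arrays compared were fitted 35 passed, 28 higher and 7 lower, with quantile normalization 9, with the stricter filter 9 and with array weights 158. Without the filter on dim probe sets 0 passed (adjusted p = 0.12 for Ccn2 and Myh7), and without a trend 2. Without week as a block Ccn2 alone passed, with adjusted p = 0.0596 for Fkbp5, 0.11 for Myh7 and 0.0825 for Pdk4. Leaving out healthy sedentary week 1 gave 2, diabetic sedentary week 3 gave 2, diabetic sedentary week 1 gave 0, and week 1 or week 5 as a whole gave 0. Pdk4 lost its call in each of these and also without healthy sedentary week 5 (adjusted p = 0.258), diabetic sedentary week 5 (adjusted p = 0.115), healthy trained week 3 (adjusted p = 0.0741) and healthy trained week 5 (adjusted p = 0.0545), and on median-centred arrays (adjusted p = 0.0929). Fkbp5 lost it without healthy sedentary week 1 (adjusted p = 0.0634) or 3 (adjusted p = 0.0889), without diabetic sedentary week 1 (adjusted p = 0.118) or 3 (adjusted p = 0.0632) and without week 3 (adjusted p = 0.0585).

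Over both disease states, training changed no transcript past the threshold. By limma 0 probe sets passed, and 0 passed under every other setting run. An unadjusted p under 0.05 was reached by 257, where 373 would be expected by chance, and by 418 without the diabetic trained array of week 3. Chpf, a chondroitin polymerizing factor (-0.69, SE 0.15), Tomm34, a mitochondrial import factor (-0.90, SE 0.19), Top1, DNA topoisomerase I (0.65, SE 0.14), and Btg2, an antiproliferative gene (-0.52, SE 0.12), had the smallest p among genes with the same sign in 6 of 6 week-matched differences. Each had adjusted p = 0.998. No list of 36 passed, with a median of -0.17 for immediate early genes and of 0.21 for erythroid cell markers (adjusted p = 0.0564 for both).

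In healthy hearts, training lowered the list of immediate early genes, which respond within minutes to stimuli (median -0.14, 13 genes, adjusted p = 0.000979, adjusted p = 0.374 with an estimated correlation). None of its genes passed over all probe sets, and adjusted over the list alone 3 were lower. These were Nr4a1, an orphan nuclear receptor (-1.03, SE 0.25), at 32 ± 6.95 in trained against 64.6 ± 5.12 in sedentary hearts (SD, n = 3 each), Btg2 (-0.58, SE 0.17) and Dusp1, a phosphatase of MAP kinases (-0.41, SE 0.13). The call was lost without week 5 (adjusted p = 0.0971) and without healthy trained week 5 (adjusted p = 0.0759). Lung markers were lower too (median -0.97, 3 genes, adjusted p = 8.8e-05, adjusted p = 0.374 with an estimated correlation), with 0 past the threshold and 2 lower adjusted over the list alone. Among them Scgb1a1, the club cell secretory protein, was at 205, 55.6 and 12.8 in healthy sedentary hearts of weeks 1, 3 and 5 and between 7.3 and 19.2 on the other 9 arrays. The call was lost without week 3 (adjusted p = 0.301).

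By limma 0 probe sets passed for healthy trained against healthy sedentary, under every setting run, with 152 at an unadjusted p under 0.05. That count was 361 without the diabetic trained array of week 3, which enters only the estimates of spread and week. Pdgfra, a growth factor receptor of fibroblasts, was at 211 ± 19.7 in trained against 133 ± 28.7 in sedentary hearts (0.68, SE 0.15, adjusted p = 0.999, n = 3 each), higher in 3 of 3 weeks.

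In diabetic hearts, training gave 0 probe sets past the threshold by limma, 1 without the diabetic trained array of week 5 and 0 under every other setting run. At an unadjusted p under 0.05 there were 533, and 379 without the diabetic trained array of week 3. Top1 was at 275.5 ± 43.3 in diabetic trained and 146 ± 37.6 in diabetic sedentary hearts (0.93, SE 0.20, adjusted p = 0.665, n = 3 each), higher in 3 of 3 weeks. Tom1, an endosomal trafficking gene (-0.64, SE 0.16), and Cic, a transcriptional repressor (-0.83, SE 0.20), were among the lower values, with the same adjusted p. No list passed, and skeletal muscle markers had the smallest adjusted p (0.105, median 0.28, 10 genes).

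The diabetes by training interaction asks whether training acts differently in diabetic and healthy hearts. By limma 0 probe sets passed, under every setting run, and 321 had an unadjusted p under 0.05. The smallest p among named genes was that of Pdgfra, whose training difference was lower in diabetic than in healthy hearts (-1.21, SE 0.22, adjusted p = 0.859), and Nr4a1 differed the other way (1.51, SE 0.35). Among lists, 2 passed. Skeletal muscle markers had a median of 0.85 over 10 genes (adjusted p = 0.0186, adjusted p = 0.467 with an estimated correlation), and lung markers of 1.39 over 3 genes (adjusted p = 0.0186, adjusted p = 0.909 with an estimated correlation). In either list 0 genes passed over all probe sets and 0 adjusted over the list alone. The diabetic trained array of week 3 held the highest Atp2a1, the fast muscle calcium pump, at 95.8 against 8.8 to 33 on the other 11. Without that array both lists still passed (adjusted p = 0.041), with medians of 0.45 and 0.97.

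Both interaction lists lost the call in other fits, with medians above 0 in each. The call of skeletal muscle markers was lost without healthy sedentary week 3 (median 0.78, adjusted p = 0.0741), diabetic trained week 5 (median 0.61, adjusted p = 0.238), healthy trained week 5 (median 0.67, adjusted p = 0.0651), week 3 (median 0.52, adjusted p = 0.203) or week 5 (median 0.75, adjusted p = 0.145), and with the stricter filter (median 0.28, adjusted p = 0.241). That of lung markers was lost without healthy sedentary week 3 (median 0.83, adjusted p = 0.0754), diabetic trained week 5 (median 1.60, adjusted p = 0.238), week 1 (median 1.13, adjusted p = 0.131) or week 3 (median 0.17, adjusted p = 0.369), and without the filter on dim probe sets (median 0.59, adjusted p = 0.181).

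The combination of diabetes and training, against healthy sedentary hearts, raised Fkbp5 2.95-fold (log2 difference 1.56, SE 0.23, adjusted p = 0.046), Pdk4 2.76-fold (1.46, SE 0.21, adjusted p = 0.0451) and Myh7 2.5-fold (1.32, SE 0.16, adjusted p = 0.0175). It lowered Camk2b (-2.23, SE 0.28, adjusted p = 0.0175), from 39.1 ± 11.4 to 8.53 ± 3.33 (SD, n = 3 each), the latter under the highest control signal. All 4 differed in 3 of 3 weeks. The second Myh7 probe set (1.56, SE 0.39) did not pass. Ccn2 (1.17, SE 0.20, adjusted p = 0.0794) and Cdh13 (-1.21, SE 0.20, adjusted p = 0.0706) did not pass. Of the lists, 3 were higher and 3 lower, all 6 among the lists named for diabetes above. The arrays compared here also entered diabetes over both training states, and the healthy sedentary ones the sedentary comparison. The overlap in genes and lists is therefore partly built in. The glucocorticoid and FoxO response list rose (median 0.34, adjusted p = 0.0013, adjusted p = 0.633 with an estimated correlation), with Fkbp5 past the threshold and 1 higher adjusted over the list alone. It lost the call without week 1 (adjusted p = 0.0525) and without diabetic trained week 5 (adjusted p = 0.0849). The heat shock and chaperone list fell (median -0.32, adjusted p = 0.00148, adjusted p = 0.639 with an estimated correlation), with 0 past the threshold and 3 lower adjusted over the list alone. It lost the call without the diabetic trained array of week 3 (median -0.15, adjusted p = 0.28) and without week 3 (adjusted p = 0.277). So did the lists of glucose use (median -0.19, adjusted p = 0.0286) and of fatty acid synthesis (median -0.29, adjusted p = 0.0286), to medians of -0.08 (adjusted p = 0.406) and -0.19 (adjusted p = 0.162) without that array and to adjusted p = 0.336 and 0.231 without week 3. Each of these 2 lists lost the call in 6 of the 15 fits without an array or a week, and with only the arrays compared (adjusted p = 0.0738 for both). No gene of either list passed over all probe sets, 5 and 1 were lower adjusted over the list alone, and with an estimated correlation adjusted p was 0.639 and 0.633.

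Fkbp5, Pdk4, Myh7 and Camk2b were all that passed for diabetic trained against healthy sedentary by limma, with 779 probe sets at an unadjusted p under 0.05. The count was 0 without week as a block (adjusted p from 0.204 for Pdk4 and Camk2b to 0.353 for Myh7), 0 in the fit of the 6 arrays alone, 0 without the filter on dim probe sets, 1 on median-centred arrays, 1 without a trend and 16 with array weights. Without the diabetic trained array of week 3, 3 passed, Myh7, Camk2b and Ccn2 (adjusted p = 0.00389), and Fkbp5 (adjusted p = 0.06) and Pdk4 (adjusted p = 0.0543) did not. Leaving out diabetic trained week 1 gave 20, and healthy trained week 5 or diabetic sedentary week 1 gave 2. Leaving out healthy sedentary week 1, 3 or 5, diabetic trained week 5, healthy trained week 1 or 3, or week 1 or 5 as a whole gave 0. The diabetes effects of the sedentary and of the trained pairs, which share no array, correlated over 7453 probe sets at r = 0.168 (Spearman rho 0.13), and at r = 0.314 without week 3 of the trained pair. This correlation is across probe sets, which are not independent replicates.

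Interferon and antigen presentation genes differed most with diabetes at week 1. In the sedentary pair their median difference was 1.11 at week 1 (21 of 22 genes higher), 0.12 at week 3 and 0.08 at week 5. In the trained pair it was 0.87 (20 higher), -0.25 and 0.07, with 1 array against 1 each. Gbp3, a guanylate-binding GTPase, had signals of 293 and 190 in the diabetic sedentary and diabetic trained hearts of week 1 and between 24.4 and 49.9 on the other 10 arrays. Psmb8, an immunoproteasome subunit, had 206 and 184 against 48.2 to 83.1. Outside the list Iigp1, an immunity-related GTPase, had 578.5 and 370 against 44 to 131.

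The interferon list's diabetes effect fell by a median of 0.24 on the log2 scale per week (camera adjusted p = 5.6e-19, adjusted p = 0.256 with an estimated correlation). Over all probe sets 0 of 22 genes passed, and 6 were lower adjusted over the list alone. Gbp3 stood at -0.68 per week (SE 0.11, adjusted p = 0.54), Psmb8 at -0.31 (SE 0.10) and Iigp1 at -0.53 (SE 0.10, adjusted p = 0.81). By limma 0 probe sets passed for a change of the diabetes effect with week, 2 with array weights, Gbp3 among them (adjusted p = 0.0227), and 0 under every other setting. At an unadjusted p under 0.05 there were 115, and 295 without the diabetic trained array of week 3. Without week 1 the list's call was lost and its median slope was 0.0119 (adjusted p = 0.965).

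**Figure D3:**
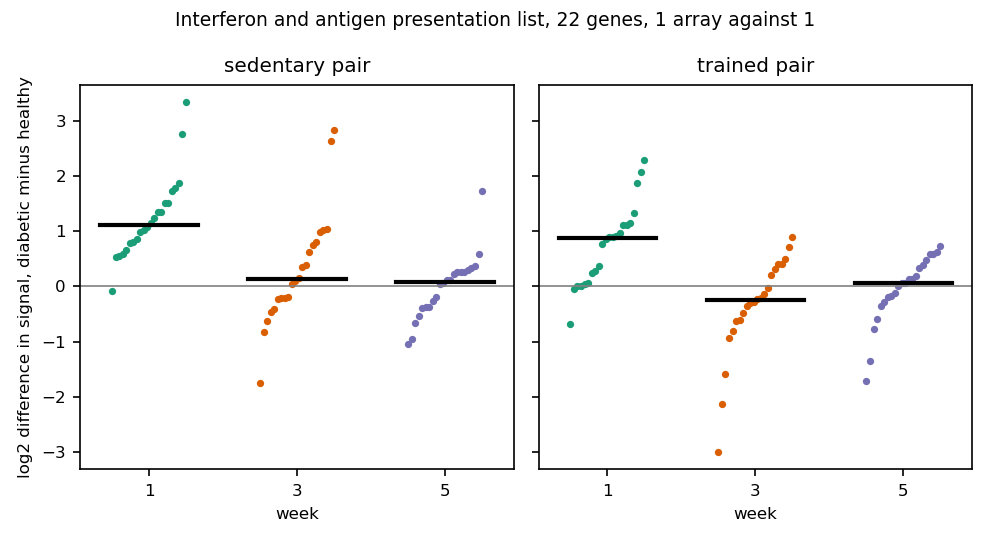
Log2 difference in signal, diabetic minus healthy (y axis), of the 22 measured genes of the interferon and antigen presentation list at weeks 1, 3 and 5 (x axis). The sedentary pair is on the left and the trained pair on the right, 1 array against 1. Each point is a gene and each black line the median, 1.11 and 0.87 at week 1 and between -0.25 and 0.12 at weeks 3 and 5.

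Between week 1 and week 5, averaged over the conditions, 8 of 57 genes of oxidative phosphorylation rose and 8 of 22 of antigen presentation and interferon response fell. Of all 7453 probe sets tested 1145 passed (631 higher, 514 lower), a share near that of oxidative phosphorylation genes past the threshold in either direction. Week 5 had its own run day and chip lot, so week and run cannot be told apart. The age of the mice is not given by week, so a difference in age cannot be set apart either. The 18S ribosomal RNA control also read higher at week 5 (1395 to 3809) than at weeks 1 and 3 (80.9 to 1141), and the actin 3'/5' ratio was 2.11 to 2.52 (median 2.23) against 1.70 to 2.46 (median 1.86). The changes below run beside these shifts in RNA signals. Cycs, cytochrome c, was higher at week 5 (1.06, SE 0.13, adjusted p = 0.00147, n = 4 each), as were the complex I subunits Ndufa6 (0.87, SE 0.14) and Ndufb3 (1.17, SE 0.23). Of 57 oxidative phosphorylation genes 8 rose, 1, Ndufv1, fell and 48 did not pass, with 8 and 1 adjusted over the list alone (median 0.12, adjusted p = 0.0227, adjusted p = 0.923 with an estimated correlation). Of 22 interferon and antigen presentation genes 8 fell, such as Tap2, a peptide transporter (-1.22, SE 0.22), and H2-K1, a class I antigen (-0.92, SE 0.19, an _f_at probe set). For that list 10 were lower adjusted over the list alone (median -0.90, adjusted p = 0.00249, adjusted p = 0.923 with an estimated correlation). The conditions differed in this: the interferon list was higher at week 1 than at weeks 3 and 5 by a median of 1.27 in diabetic hearts, against 0.31 in healthy hearts. Hibch (1.11, SE 0.18), Mmut, Dbt and Hibadh rose among 11 genes of branched-chain amino acid breakdown and 7 did not pass, with 4 higher adjusted over the list alone (median 0.23, adjusted p = 0.0313, adjusted p = 0.923 with an estimated correlation).

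Leaving out an array ended the calls of these week lists. Oxidative phosphorylation lost it without healthy sedentary week 1 (adjusted p = 0.108), diabetic sedentary week 1 (adjusted p = 0.136) or diabetic sedentary week 5 (adjusted p = 0.0776), with quantile normalization (adjusted p = 0.0506) and with the stricter filter (adjusted p = 0.0552). Interferon and antigen presentation lost it without diabetic sedentary week 1 (adjusted p = 0.0786) or 5 (adjusted p = 0.0776). Branched-chain amino acid breakdown lost it without healthy sedentary week 1 (adjusted p = 0.0872) or 5 (adjusted p = 0.0632), without diabetic sedentary week 1 (adjusted p = 0.136) or 5 (adjusted p = 0.0776), with quantile normalization (adjusted p = 0.0506) and with the stricter filter (adjusted p = 0.126).

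The largest single rises by week 5 with the same sign in 4 of 4 conditions were those of C1d, a nuclear exosome cofactor (1.99, SE 0.34), Tspan12, a tetraspanin (1.99, SE 0.21), Gpcpd1, a choline phosphodiesterase (1.88, SE 0.20), Rab10, a vesicle GTPase (1.82, SE 0.18), and Cryz, a quinone reductase (1.78, SE 0.36). The largest falls were those of H2-Q5, a class I antigen (-2.32, SE 0.48, an _f_at probe set), Gdap10 (-1.98, SE 0.26), Mau2, a cohesin loader (-1.91, SE 0.25), Tcf25 (-1.86, SE 0.35) and Ago2, an Argonaute protein (-1.80, SE 0.21). A second Rab10 probe set passed (0.97, SE 0.21) and a second Tcf25 probe set did not (-1.14, SE 0.53). The lower mean of Cryz, H2-Q5, Mau2 and Tcf25 lay under the highest control signal.

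In total 1145 probe sets passed for week 5 against week 1 by limma, 631 higher and 514 lower, with a median difference over all probe sets of -0.10. Centring on the array medians gave 600 higher and 289 lower, no filter on dim probe sets 650 in all and array weights 2683. Leaving out the diabetic trained array of week 3 gave 2406, and leaving out week 3 gave 2252. Leaving out an array of week 1 gave 276 (healthy trained), 469 (diabetic sedentary), 510 (diabetic trained) and 742 (healthy sedentary). For week 5 the counts were 272 (healthy trained), 367 (diabetic trained), 539 (healthy sedentary) and 1200 (diabetic sedentary).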

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

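The tests of background and RNA degradation on the diabetic trained array of week 3, and of a run-day effect at week 1, were chosen only after the pattern was seen. The others were fixed before they were run, but the patterns of lung markers and interferon genes that they address came from these data.

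The lists of skeletal muscle markers (median interaction 0.85) and lung markers (1.39) stood out because they passed the test of the interaction with a preset correlation between genes. Neither passed with an estimated correlation (adjusted p = 0.467 and 0.909), and both lost the call without healthy sedentary week 3 (0.0741 and 0.0754, medians 0.78 and 0.83) or diabetic trained week 5 (0.238 for both, medians 0.61 and 1.60), skeletal muscle markers also without healthy trained week 5 (0.0651, median 0.67). The interferon and antigen presentation list stood out because it passed the test of a change of the diabetes effect with week, at -0.24 on the log2 scale per week. It did not pass with an estimated correlation (adjusted p = 0.256), and without week 1 its median slope was 0.0119 (adjusted p = 0.965). Fewer than 4 arrays per condition gave no test of single arrays far from their group.

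Lung markers were lower in healthy trained and in diabetic sedentary than in healthy sedentary hearts. For healthy trained hearts the list kept its call without each healthy sedentary array in turn (highest adjusted p 0.0101), and lost it without all of week 3 (0.301). These fits used the preset correlation of 0.01, and with an estimated one the list did not pass on all arrays (adjusted p = 0.374). Whether single arrays decide the difference stays open, since Scgb1a1 stood highest on healthy sedentary week 1 and Ager on healthy sedentary week 3. For diabetic sedentary hearts the lung markers list kept its call without each healthy sedentary array too, but without that of week 3 its median was -0.33 in place of -0.89 (adjusted p = 0.0459). Traces of lung tissue in some heart pools may account for it, since Scgb1a1 is abundant in airways, but the 3 markers correlated with each other at a mean of only 0.467 over the 12 arrays after removal of week, which decides neither way. Ager stood at 34.3 on the diabetic trained array of week 3 and at 38.6 on healthy sedentary week 3, with 7 to 15.5 on the others. A response of lung-type genes in the heart to training or diabetes was not tested.

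Interferon and antigen presentation genes were highest in both diabetic pools of week 1. Macrophage and neutrophil markers differed there by a median of 0.35 in the sedentary pair and -0.15 in the trained pair, and T cell and thymus markers by 0.03 and 0.67 (3 genes). More immune cells in those pools may account for part of the difference, which these values do not decide. A run-day effect of week 1 would reach healthy hearts too, and these were higher at week 1 than at weeks 3 and 5 by a median of 0.31, against 1.27 in diabetic hearts, which leaves a part of it open. An early response to diabetes or to streptozotocin stays among the open explanations, untested, because each week had 1 pool per condition and the diabetic pools of week 1 were the closest to the injection.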

How the results depend on the processing

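Except for the tests chosen after the pattern was seen that are named in the other parts, all alternatives were fixed before the data were examined. All 42 results past a threshold for named genes, with a gene counted once in each comparison it passed, kept their direction in every alternative and every leave-one-out fit. This says little about stability, since genes were named only with the same sign in every week-matched difference. Of the 42, 12 kept their call in every alternative that held them and 8 in every leave-one-out fit run. All 8 were genes of week 5 against week 1, a comparison that cannot be told apart from run day and chip lot. So were those of the 12 other than Pdk4, Myh7 and Ccn2 for diabetes over both training states. The genes did not face the same fits. Week genes had 13 leave-one-out fits and diabetes genes 15, as week 1 or 5 could not be left out whole for the former. Pdk4, Myh7 and Ccn2 lost the call only without week 5. Of the 12, C1d, Cryz, Mau2 and Tcf25 were held by 9 alternatives, against 10 for the other week genes. The medians of 3 lists changed sign, each with its call lost: antioxidant and metallothionein for diabetes without week 5 (-0.00664, up to 0.14 over arrays and weeks left out), matrix proteases, inhibitors and TGF-beta for diabetic against healthy sedentary hearts without healthy sedentary week 1 (-0.000169, up to 0.25), and interferon and antigen presentation for the change with week without week 1 (0.0119, down to -0.44 without week 5). The smaller the group of arrays, the more a single pool weighs; leaving out an array also lowers the degrees of freedom, and the cause of other moves was not tested.

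Below, diabetic sedentary, diabetic trained and healthy trained stand for the comparisons with healthy sedentary hearts. Without week as a block (no pairing), the counts were 10 for diabetes, 1 for diabetic sedentary and 0 for diabetic trained against healthy sedentary, 2 lists for the change with week and 12 for diabetic sedentary. No list lost its call without it; week 5 against week 1 and its lists were not run so. Median centring gave 12 for diabetes and 1 for diabetic trained against healthy sedentary, and quantile normalization 9 for diabetic sedentary. No dim filter gave 6, 0 and 0 for diabetes, diabetic sedentary and diabetic trained, 650 for week 5 against week 1 and 1 list for the interaction. The stricter filter gave 9 for diabetic sedentary, and 1, 0 and 3 lists for healthy trained, the interaction and the change with week. Lung markers were not tested with the stricter filter, which left too few of their genes, so their absence there is not a lost call. Without a trend there were 9, 2 and 1 for diabetes, diabetic sedentary and diabetic trained, and with array weights 192, 158 and 16, 2 for the change with week and 2683 for week 5 against week 1. Only the arrays compared gave 35 and 0 for diabetic sedentary and diabetic trained. Scan day as a block, which only sets aside the diabetic trained array of week 3, gave 151, 61 and 2407 for diabetes, diabetic sedentary and week 5 against week 1, and 7 lists for the interaction. An adjusted p under 0.10 gave 133, 9, 8 and 1880 for diabetes, diabetic sedentary, diabetic trained and week 5 against week 1, and 17 lists for diabetic sedentary. With an estimated correlation 0 lists passed for diabetes, diabetic sedentary, healthy trained, the interaction and the change with week.

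Over arrays and weeks left out in turn, the probe set counts ranged from 0 to 153 for diabetes, 0 to 60 for diabetic sedentary, 0 to 20 for diabetic trained against healthy sedentary, 0 to 1 against diabetic sedentary and 272 to 2406 for week 5 against week 1; lists ranged from 9 to 13 for diabetes, 6 to 14 for diabetic sedentary, 1 to 5 for healthy trained, 0 to 7 for the interaction and 1 to 4 for the change with week. Lists were not run with array weights or without a trend. Signals near the highest bacterial or yeast control, 13.8, limit folds of dim probe sets.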

Other observations

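The tests of background and RNA degradation on the diabetic trained array of week 3 were chosen only after the pattern was seen. The others were fixed before they were run, except for the reading of 1 bound named below.

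Genes of the adult and fetal heart programmes other than Myh7 did not pass for diabetes, as values picked after they were seen. Myh6, the fast alpha-myosin heavy chain, was at 4340 in healthy sedentary and 3216 in diabetic sedentary hearts (-0.27 over both training states, SE 0.12, adjusted p = 0.4). Nppa (0.35, SE 0.13) and Nppb (0.64, SE 0.25), the natriuretic peptides, had adjusted p = 0.3 and 0.33. Acta1, skeletal alpha-actin, was at 801 in healthy sedentary and 299.5 in diabetic sedentary hearts (-1.08 over both training states, SE 0.26, adjusted p = 0.09). The hypertrophy and fetal gene programme list had a median of -0.01 over 12 genes, 6 higher and 6 lower, of which Myh7 alone passed.

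Tricarboxylic acid cycle genes had a median diabetes difference of -0.10 over 19 genes, calcium handling genes -0.08 over 15, sarcomere genes -0.11 over 22, circadian clock genes 0.07 over 13, and angiogenesis genes -0.02 over 22, and none of these lists passed.

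The diabetic trained array of week 3 stood apart from the other 11. Degraded RNA in that pool is argued against by 3'/5' signal ratios of 1.80 for actin and 1.06 for Gapdh, inside the ranges of the other 11 arrays (1.70 to 2.52 and 1.03 to 1.25). The labelling and hybridisation run is a candidate explanation: 19 bacterial and yeast control probe sets, which no mouse RNA should bind, read a median of 1.21 higher (log2) than on the other arrays, where each array's own excess lay between -0.70 and 0.26. These controls are dim, so that log2 value is uncertain. Their median signal was 6.2 on that array against 0.7 to 5.2 on the other 11, and their highest 13.8 against 7.1 to 13.3. The brightest mouse probe set read 9568 there against 4030 to 5460. Against the other arrays of week 3, the dimmest 20% of probe sets read a median of 0.58 higher on the log2 scale and the brightest 20% a median of -0.42. A response of diabetic trained hearts at week 3 stays open. The array's deviation correlated over probe sets with those of diabetic trained weeks 1 and 5 at 0.024 and -0.0531, under the bound of 0.1 set beforehand for arguing against it. Since weeks 1 and 5 correlated with each other at only 0.0631, the reading of this bound was changed after the result was seen, to one that decides neither way.

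Other splits of the arrays were fitted in the same way. For diabetes over both training states, in a fit without the interaction, the real split gave 65 probe sets and 2 of 100 splits, the real one included, gave as many. Most of these splits are uneven within weeks, which the fit removes, and so are no fair match for the real one. Of the 25 with 2 arrays of each week on either side, 2 gave as many (a share of 0.08), the real one included, so chance cannot be excluded by this count. The highest other split, with 759, was sedentary against trained with the diabetic arrays of week 3 exchanged. Beside the training term that split rests on the array that stood apart, so it points to a structure of the samples. The highest of the 75 uneven splits gave 2. For training over both disease states and for the interaction the real count was 0, which every one of 100 splits must reach, so their count says nothing about chance. The highest others were 355 and 1220, and that with 1220 was the same exchange. For the comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05: the real count and the highest other were 4 and 0 for diabetic sedentary (1 split as large) and for diabetic trained against healthy sedentary (1 as large), and 0 and 0 for healthy trained against healthy sedentary and diabetic trained against diabetic sedentary (10 as large in both). For week 5 against week 1, 1 of 35 splits gave as many as the real 1145, with 1 in the highest other. Only 8 of them part the arrays of each condition as the real one does, too few for a share under 0.05 (real 1145, highest other 0), and a run day would follow the real split too.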
